A study of Aliivibrio fischeri with 2 samples.

How the data were processed

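RtmR iCLIP was carried out on 2 biological replicates of 1 strain, which form the only group. Per the labels' protocols, cultures grown in LBS medium were irradiated at 254 nm with 800 mJ per square centimetre, lysed with beads, treated with RNase I at a high or a low dose to trim the RNA, and immunoprecipitated with an anti-FLAG antibody. The protocols also mention a non-specific mouse antibody, and no library made with it was used here. How the RNase doses were combined into each library is not given in the sources used here.

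The authors deposited 1 peak list per replicate, so peaks were taken as called per replicate and not on pooled reads. Each line holds a replicon (chromosome I, chromosome II or plasmid pES100), a start, an end, a gene name, a score and a strand. STAR, a read aligner, is named per the submitters' processing notes, with no version or role. The peak caller, its threshold, the genome build, the annotation, the removal of duplicate reads and what the score counts are not given in the sources used here. The score deposited by the authors is, from the values, a whole number of at least 1 per peak, not scaled between replicates, and it was used only to describe, rank or filter peaks and as shares within each list. From the values, no pair of peaks on a strand lay closer than 4 nt, every peak had a gene name, and all peaks of a gene lay on 1 strand. Replicate 1 had 534 peaks with a score of 1 (6.00%) and replicate 2 had 495 (6.45%). The lists shared 367 peaks with identical borders, 27 of them with identical scores, so they were treated as separate libraries.

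Gene names came from the lists and were matched by locus tag to the RefSeq gene table of assembly ASM1180v1, which served only for symbols, gene classes and which genes neighbour each other. None of its coordinates is printed, because the lists name no build. Of 2232 genes named in the lists, 2217 (99.3%) were matched and 15 were not. In each replicate 3 peaks carried the names of several genes, and these were left out of sums per gene. The table holds 3953 genes, of which 3748 are protein-coding and 1259 of those have a symbol.

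Peaks were called shared when they overlapped on the same strand by at least 1 nt. The overlap was set against 1000 circular shifts along each replicon and against 1000 random placements within the span of each gene's peaks, a replacement for placement within annotated gene borders. Gene scores were compared as shares of each replicate's summed score, on the log2 scale with no pseudocount and over genes with peaks in both replicates, with 1000 bootstrap draws over genes for the interval. Shares of peaks have exact Clopper-Pearson 95% intervals. These intervals cover the counting of peaks only, since the number of reads behind a list is unknown. They also treat the peaks of a gene as independent, so they may be too narrow.

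Gene lists were tested with Fisher's exact test, two-sided, on genes with peaks in both replicates against all protein-coding genes, with Benjamini-Hochberg adjustment over 17 lists and a threshold of 0.05. The adjustment was over 16 lists for the symbol background, where syp has no members, and over 18 tests for lists with at least 5 members on a chromosome. Odds ratios in those tests have 0.5 added to each cell. The lists of syp genes, biofilm regulators, cellulose, light production and quorum sensing, flagella and chemotaxis, and glycolysis and the tricarboxylic acid cycle, 6 in all, were fixed before the data were examined. Of 14 lists planned by words of the gene product, 11 were replaced by lists of gene symbols after the files had been seen, because the table gives no products, and 3 were not run (cyclic di-GMP, two-component systems, and products named as membrane). The product words of the cellulose, quorum-sensing and flagellar lists were likewise not used.

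The rule for named genes was fixed before the data were examined. It took the 20 genes outside rRNA and tRNA with the highest mean share of score among genes with peaks in both replicates, the RNA genes other than rRNA and tRNA, VF_2432, all syp genes and biofilm regulators with a peak, up to 4 genes of every other list, and the 5 genes with the largest ratio each way between replicates among the 200 genes of highest share. Positions along coding sequences, sequence at peaks, gene windows and lists matched on gene length were planned and are not analysed here, as no genome of the lists' build was used.

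Alternatives were the upper 50% or top 10% of scores, other definitions of a shared peak, the highest peak in place of the summed score, removal of rRNA and tRNA genes, at least 2 peaks per replicate, other backgrounds for the lists, and each replicate alone. Chosen after seeing the data were a lowest score of 5, the symbol and chromosome backgrounds, the gene names of the peak lists, the gene blocks, and the comparison between replicons. The scripts were tested on simulated data. In 20 simulated copies of the 8899 peaks of replicate 1 with 60% kept in place, the overlap found was 60.2% on average. In 100 simulated sets of 3748 genes, a list of 53 genes bound at 90% against 40% was called in 100% of sets, and 0.857% of unchanged lists were called. Simulated genes were bound independently of their neighbours and lists were filled at random. These rates therefore do not cover lists whose members lie in runs of neighbouring genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with fixed random seeds.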

Results

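RNA recovered with tagged RtmR after crosslinking was mapped in Aliivibrio fischeri, the bioluminescent bacterium that forms a symbiosis with the Hawaiian bobtail squid. RtmR, encoded by VF_2432, is described by the series title as an RNA-binding protein of the RRM (RNA recognition motif) family that sits in the membrane and regulates biofilm formation. The method was iCLIP, in which ultraviolet light links a protein to the RNA it touches, the protein is pulled down, and the attached RNA fragments are sequenced. The strain derived from the squid isolate ES114, lacked its own VF_2432, carried a 3XFLAG-tagged copy at the attTn7 site, and carried the biofilm-inducing allele rscS*. The design held 1 group with 2 biological replicates, and no library from an untagged strain, a control antibody or input RNA was used here. RNA bound by RtmR can therefore not be told apart from RNA carried through the pull-down without binding it. Replicate 1 had 8899 peaks with a summed score of 232729 over 57188 nt, and replicate 2 had 7677 peaks with a summed score of 196572 over 48748 nt. The score is the authors' own value per peak, and it had a median of 11 in replicate 1 and 10 in replicate 2. Peaks were narrow, with a median width of 5 nt in both replicates, and none exceeded 80 nt. The read depth behind each list is unknown, so the intervals given below cover the counting of peaks only. Intervals for shares of peaks also treat the peaks of a gene as independent and may be too narrow.

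The first question was which RNAs carried peaks. The 20 genes with the highest shares of peak score included the ribosomal protein gene rplE and genes of respiration and of carbon metabolism. Leaving out rRNA and tRNA genes, mdtL (VF_0041), named for a multidrug transporter, held 1.65% ± 0.36 of the peak score (SD, n = 2), and raiA (VF_0562), a ribosome hibernation factor, held 1.59% ± 0.33. The next genes were sucA (VF_0823) of 2-oxoglutarate dehydrogenase at 1.42% ± 0.13, acs (VF_2383), encoding acetyl-CoA synthetase, at 1.09% in replicate 1 and 1.41% in replicate 2, acnB (VF_2158), encoding aconitase, at 1.22% ± 0.021, and rplE (VF_0249), encoding ribosomal protein L5, at 1.19% ± 0.0021. Together the top 20 genes held 21.1% ± 1.6 of that score (SD, n = 2). These shares are not scaled to RNA abundance or gene length.

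The other members of the top 20 are listed by the function their names give, where known, and no grouping was tested. VF_2651, also among them, is described below with the RNA genes. The sodium-translocating NADH:quinone reductase genes nqrB (VF_0726) and nqrA (VF_0725) held 1.10% ± 0.22 and 0.850% ± 0.078, sdhA (VF_0821) of succinate dehydrogenase held 0.866% ± 0.075, and the ATP synthase genes atpE (VF_2569) and atpA (VF_2566) held 0.800% ± 0.14 and 0.703% ± 0.029. Carbon metabolism added gapA (VF_0913), encoding glyceraldehyde-3-phosphate dehydrogenase, at 0.905% ± 0.079, pck (VF_2478), encoding phosphoenolpyruvate carboxykinase, at 0.870% ± 0.32, and aceE (VF_2181) of pyruvate dehydrogenase at 0.721% ± 0.042. Gene expression machinery added rpoB (VF_2414), encoding an RNA polymerase subunit, at 1.08% ± 0.082 and fusA2 (VF_0529), encoding an elongation factor G, at 0.930% ± 0.15. VF_1065 held 1.18% ± 0.12, VF_2218 held 0.770% ± 0.28, and VF_A1190, whose tag was not matched to the reference table, held 1.02% ± 0.10. Of these 20 genes, 18 were also in the top 20 of replicate 1 alone and 18 in that of replicate 2 alone, while 13 remained when genes were ranked by their highest peak.

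**Figure D1:**
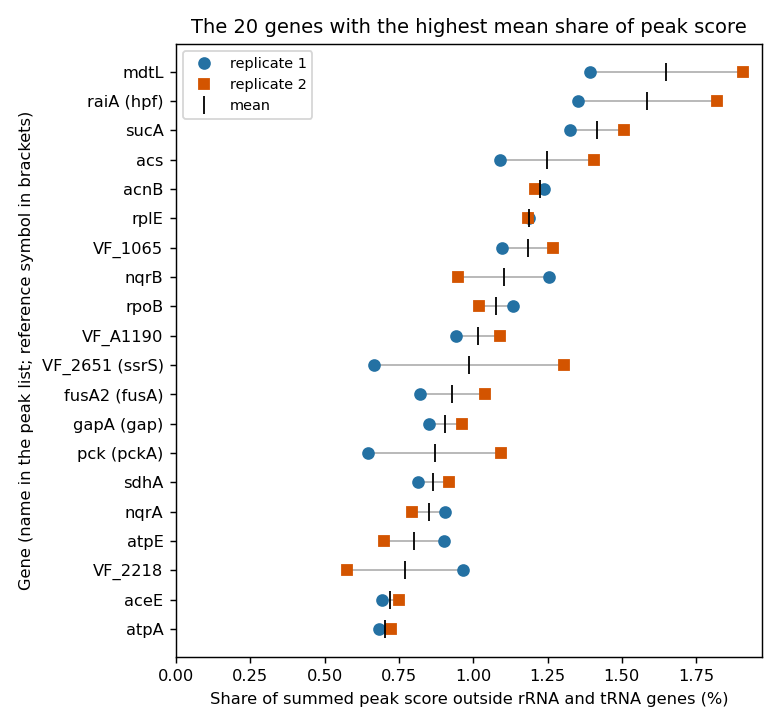
Share of summed peak score outside rRNA and tRNA genes (percent, x axis) for the 20 genes with the highest mean share (y axis). Circles are replicate 1, squares replicate 2 and vertical ticks their mean, and mdtL leads with 1.39% in replicate 1 and 1.91% in replicate 2.

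Some of these RNAs were covered by many peaks and others by a single one. On raiA the whole score came from 1 peak with the same borders in both replicates, on chromosome I from 610568 to 610607 on the minus strand, scored 3092 in replicate 1 and 3488 in replicate 2. It was the highest peak of either list. On sucA, 21 peaks were present in each replicate and the highest scored 2053 and 1841. On acnB the score was spread over 40 peaks in replicate 1 and 38 in replicate 2, the highest of which scored 360 and 265. The highest peak of rpoB in replicate 1 spanned 2703563 to 2703642 on the minus strand of chromosome I and scored 806. All positions are counted from 1 as in the authors' lists, whose genome build is not given in the sources used here, and whether a peak lay in a coding or an untranslated part of its gene was not analysed here.

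The second comparison asked which kinds of RNA gene carried the peaks. Protein-coding genes held 97.8% ± 0.16 of the peaks (SD, n = 2) and 93.3% ± 1.5 of the summed score. RNA genes other than rRNA and tRNA held 0.200% ± 0.012 of the peaks but 2.23% ± 0.75 of the score, and all 4 such genes of the reference table had peaks in both replicates. These were VF_2651 (ssrS), the 6S RNA that binds RNA polymerase, VF_2599 (ffs), the RNA of the signal recognition particle that targets proteins to the membrane, VF_2654 (rnpB), the RNA of ribonuclease P, and ssrA (VF_2639), the tmRNA that rescues stalled ribosomes. VF_2651 held 0.985% ± 0.45 of the score outside rRNA and tRNA genes, with 4 peaks in each replicate scoring 1523 over 42 nt and 2499 over 41 nt in sum. VF_2599 held 0.539% ± 0.19, VF_2654 held 0.405% ± 0.070 and ssrA held 0.351% ± 0.064. On VF_2599 the highest peak ran from 1087845 to 1087865 on the minus strand of chromosome I in both replicates and scored 582 and 960.

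tRNA genes held 0.573% ± 0.11 of the peaks and 2.03% ± 0.46 of the score, and 27 of the 119 tRNA genes had peaks in both replicates. rRNA genes held 0.291% ± 0.030 of the peaks and 0.121% ± 0.0042 of the score. Pseudogenes of the reference table held 0.851% ± 0.012 of the peaks and 0.747% ± 0.016 of the score. Genes not matched to it held 0.277% ± 0.0052 of the peaks but 1.54% ± 0.28 of the score. Exact 95% binomial intervals for the protein-coding share of peaks were 97.6% to 98.2% in replicate 1 and 97.3% to 98.0% in replicate 2. Values for rRNA, tRNA and other genes with near-identical copies, such as tufA and tufB, are uncertain because how reads with several matches were placed is not given in the sources used here. Every peak carried the name of a gene, so RNA antisense to genes or between genes was not analysed here.

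The third comparison asked whether defined groups of genes carried peaks more or less often than other protein-coding genes. Genes of central carbon metabolism and of the translation apparatus carried peaks in both replicates more often than other genes, and genes for flagella and chemotaxis did so less often. All 20 genes of glycolysis and the tricarboxylic acid cycle had peaks in both replicates, against 40.4% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 8.354e-08 over 17 lists), and they held 7.73% ± 0.20 of the score (SD, n = 2). In this list acnB, sucA, gapA and sdhA had the highest shares. Of 33 flagellar and chemotaxis genes, 5 had peaks in both replicates, or 15.2% against 41.0% (Fisher's exact test, odds ratio 0.28, adjusted p = 0.0052). The highest flagellar shares were those of flhF (VF_1836) at 0.0612% ± 0.0042 and flhA (VF_1837) at 0.0189% ± 0.0020.

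Of 11 further lists, chosen by gene symbol after the files had been seen, 8 carried peaks more often than other protein-coding genes. Outside the ribosomal list, 56.1% of genes with a symbol had peaks in both replicates, against 40.0% of all protein-coding genes. The background of all protein-coding genes therefore favours lists built from symbols. With only genes that have a symbol as background, 4 lists still passed as carrying peaks more often. They were ribosomal proteins, translation factors and tRNA ligases, respiration, and polysaccharide synthesis. Ribosomal protein genes had peaks in both replicates for 49 of 53 members (Fisher's exact test, odds ratio 16.5, adjusted p = 3.347e-14), with rplE, rpsA (VF_1759), rpsH (VF_0251) and rplS (VF_0552) highest, and held 5.88% ± 0.55 of the score (SD, n = 2). Translation factors and tRNA ligases, among them thrS (VF_1214), tsf (VF_1961) and ileS (VF_0467), had peaks in both for 31 of 35 members (odds ratio 10.4, Fisher's exact adjusted p = 4.195e-08). Respiratory complexes and ATP synthase, had peaks in both for 22 of 25 members (odds ratio 9.47, Fisher's exact adjusted p = 5.449e-06). Of its members sdhA, atpE, atpA and cydA (VF_0953) were highest, and nqrB and nqrA are not members because the reference table gives them no symbol. Polysaccharide and lipopolysaccharide synthesis had 25 of 31 (odds ratio 5.78, Fisher's exact adjusted p = 2.737e-05), led by the sialic acid synthesis genes neuB (VF_0143) and neuC (VF_0142), with ddhC (VF_0184) and lpxC (VF_2195). Chaperones and proteases had 22 of 29 (odds ratio 4.41, Fisher's exact adjusted p = 0.00050), led by clpA (VF_1765), hflB (VF_0479), prc (VF_1280) and hslV (VF_2277). In the top 10% of scores 2 of these lists did not pass. They were translation factors and tRNA ligases (6 of 35, odds ratio 2.63, Fisher's exact adjusted p = 0.145) and polysaccharide synthesis (5 of 31, odds ratio 2.47, Fisher's exact adjusted p = 0.218).

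Among envelope and transcription genes, 18 of 26 genes for outer membrane proteins and lipoproteins had peaks in both (odds ratio 3.19, Fisher's exact adjusted p = 0.0090), including ompU (VF_0475), imp (VF_0289), pal (VF_0963) and tolB (VF_0962). Protein export had 13 of 19, including secY (VF_0257), secA (VF_2193), secD (VF_1967) and yajC (VF_1968), with an odds ratio of 3.04 (Fisher's exact adjusted p = 0.0307, and 0.0971 in replicate 2 alone). Transcription machinery had 12 of 17, including rpoB, rpoC (VF_2412), nusB (VF_0704) and rpoD (VF_2254), with an odds ratio of 3.32 (Fisher's exact adjusted p = 0.0352, and 0.0644 in replicate 1 alone). It did not pass in the upper 50% of scores (4 of 17, odds ratio 1.07, Fisher's exact adjusted p = 1) or with at least 2 peaks in each replicate (odds ratio 1.86, Fisher's exact adjusted p = 0.334). Against the other genes of chromosome I none of these 3 lists passed (Fisher's exact adjusted p = 0.196, 0.159 and 0.0734 in the order given), with odds ratios of 1.95, 2.22 and 2.98. Transporters, among them oppC (VF_1595) and putP (VF_A0829), had 41 of 82 (Fisher's exact adjusted p = 0.126, and 0.0213 in replicate 1 alone), and RNA metabolism, with pnp (VF_0490), rnr (VF_2314), rne (VF_1748) and hfq (VF_2323), had 17 of 31 (Fisher's exact adjusted p = 0.169, and 0.0061 in replicate 2 alone). Neither passed with at least 1 peak in each replicate. Transporters passed with at least 2 peaks in each (34 of 82, odds ratio 1.88, Fisher's exact adjusted p = 0.0158) and among the genes of chromosome II (12 of 24, odds ratio 3.08, Fisher's exact adjusted p = 0.0171). Among the genes of chromosome I they did not pass (29 of 58, odds ratio 1.07).

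Pilus genes gave a value that rested on how members were named. The type IV pilus list had peaks in both replicates for 2 of 20 members (odds ratio 0.20, Fisher's exact adjusted p = 0.0092), which were mshL (VF_0359) and mshJ (VF_0357). It did not pass against the other genes of chromosome I (2 of 8, odds ratio 0.41, Fisher's exact adjusted p = 0.348) or of chromosome II (0 of 12, odds ratio 0.12, Fisher's exact adjusted p = 0.0734). Adding genes that carry a pilus name only in the peak lists brings in only genes with a peak in at least 1 replicate, which by construction favours a higher odds ratio, and it was 1.08 (17 of 40 members). That value is no test of pili, and whether pilus genes differ from other genes is left open. The same addition gave 11 of 43 for flagella and chemotaxis (odds ratio 0.51, Fisher's exact adjusted p = 0.068). All 54 protein-coding genes of the flagellar and chemotaxis block from VF_1826 to VF_1881, taken whatever their names and after their values were seen, had peaks in both for 9 (16.7%), against 49.1% of other genes of chromosome I (odds ratio 0.22). Another block, VF_0356 to VF_0371 with the MSHA pilus genes, went the other way, with 12 of 16 against 48.3% (odds ratio 2.98). Both blocks were drawn around genes whose values had been seen, so they are described and not read as tests.

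Without input RNA, these tests cannot separate binding from the abundance or length of an RNA. They also count each gene as independent, while neighbouring genes carried peaks together (873 pairs, against 670 on average in permutations, described below). Members of several lists lie in runs of such neighbours, among them ribosomal, ATP synthase and sdhC to sucD genes. The p-values of the lists are therefore likely too small, by an unknown amount. Against genes with a symbol alone, the chaperone, outer membrane, export and transcription lists no longer passed (Fisher's exact adjusted p = 0.112, 0.480, 0.483 and 0.480). Genes with a peak in either replicate, as a background, hold only genes that already carry a peak. That setting tests whether peaks recur in the other replicate and not how often a list carries peaks. There 3 lists passed, those of glycolysis and the tricarboxylic acid cycle, ribosomal proteins, and respiration.

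The fourth comparison concerned the biofilm genes named by the study's subject. Peaks were present on 4 of the 18 syp genes in both replicates, and on 5 of 7 biofilm regulators outside that locus. The syp locus encodes the symbiosis polysaccharide, the main matrix sugar of the A. fischeri biofilm. The syp genes with peaks in both were sypE (VF_A1024), sypF (VF_A1025), sypG (VF_A1026) and sypR (VF_A1037), sypH (VF_A1027) had 2 peaks in replicate 2 and none in replicate 1, and the other 13 had none in either list. The share of syp genes with peaks in both, 22.2% against 40.8% of other genes, did not pass the test (odds ratio 0.45, Fisher's exact adjusted p = 0.169). In replicate 1 alone it did, with 4 of 18 syp genes (odds ratio 0.30, Fisher's exact adjusted p = 0.0241). Against the other protein-coding genes of chromosome II, which holds the locus, 25.1% of which had peaks in both, the odds ratio was 0.93 (Fisher's exact adjusted p = 1).

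SypF, a sensor kinase, and SypG, a response regulator, had the highest syp shares. On sypF, 7 peaks in each replicate summed to 105 over 52 nt in replicate 1 and 58 over 26 nt in replicate 2, a share of 0.0381% ± 0.011 (SD, n = 2). Its highest peak, at 1155407 to 1155423 on the plus strand of chromosome II in replicate 1, scored 50 and overlapped a peak scored 14 in replicate 2. On sypG, 6 and 5 peaks gave 0.0203% ± 0.00083, and the peak at 1158034 to 1158042 scored 21 in replicate 1 and overlapped one scored 18 in replicate 2. On sypE and sypR, 1 peak each was present in each replicate, and those of sypR shared the borders 1171537 to 1171541. These peaks were weak, scored 16 and 9 on sypE and 10 and 7 on sypR, near the list medians of 11 and 10. In the upper 50% of scores 2 of 18 syp genes had peaks in both replicates, and in the top 10% 0 of 18.

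The regulator with the most peak score was rscS (VF_A0237), which encodes the sensor kinase upstream of syp and is present in this strain as rscS*. It had 17 peaks summing to 286 over 132 nt in replicate 1 and 11 peaks summing to 157 over 75 nt in replicate 2, a share of 0.104% ± 0.031 (SD, n = 2). A stretch of 903 nt without peaks split them, a feature chosen after the values were seen. Peaks beyond it, from 263395 to 263707 on the minus strand of chromosome II in replicate 1 and 263424 to 263710 in replicate 2, held 83.9% and 78.3% of the gene's score. For a gene on the minus strand this is the upstream end of the peaks. Shares are not scaled to RNA abundance or gene length, and the amount of rscS RNA in this rscS* strain is not known here. The lead of rscS among the regulators is therefore not read as stronger binding.

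The other biofilm regulators with peaks in both replicates had lower shares. They were litR (VF_2177), a quorum-sensing transcription factor, at 0.0268% ± 0.0091 (SD, n = 2), hahK (VF_A0072), a sensor kinase, at 0.0266% ± 0.0073, binK (VF_A0360), a sensor kinase that inhibits biofilm formation, at 0.0262% ± 0.010, and vpsR (VF_0454) at 0.0083% ± 0.0074. luxU (VF_0938) had 2 peaks in replicate 1 and none in replicate 2, and hnoX (VF_A0071) had none in either list. The share of regulators with peaks in both, 71.4%, did not differ from other genes by the test (Fisher's exact adjusted p = 0.169). Requiring at least 2 peaks in each replicate kept 5 of 7, against 27.7% of other genes (odds ratio 5.73, Fisher's exact adjusted p = 0.0311). That count includes vpsR, whose 2 peaks in replicate 2 scored 5 and 1. In the upper 50% of scores 4 of 7 had peaks in both replicates (odds ratio 4.14, Fisher's exact adjusted p = 0.0921). In the top 10% of scores 0 of 7 did.

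Peaks were also listed on VF_2432, the gene of RtmR itself. Replicate 1 had 6 peaks summing to 186 over 54 nt and replicate 2 had 3 peaks summing to 61 over 27 nt, a share of 0.0566% ± 0.035 (SD, n = 2), and all 3 peaks of replicate 2 overlapped a peak of replicate 1. They lay between 2732191 and 2732330 on the plus strand of chromosome I, with the highest at 2732240 to 2732258 (score 64) and 2732191 to 2732205 (score 63) in replicate 1. The native gene is deleted in this strain, which carries the tagged copy at the attTn7 site. These peaks therefore do not describe an intact native transcript, and the lists do not separate the tagged copy from any native sequence left. The reference table lists VF_2432 as a pseudogene.

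**Figure D2:**
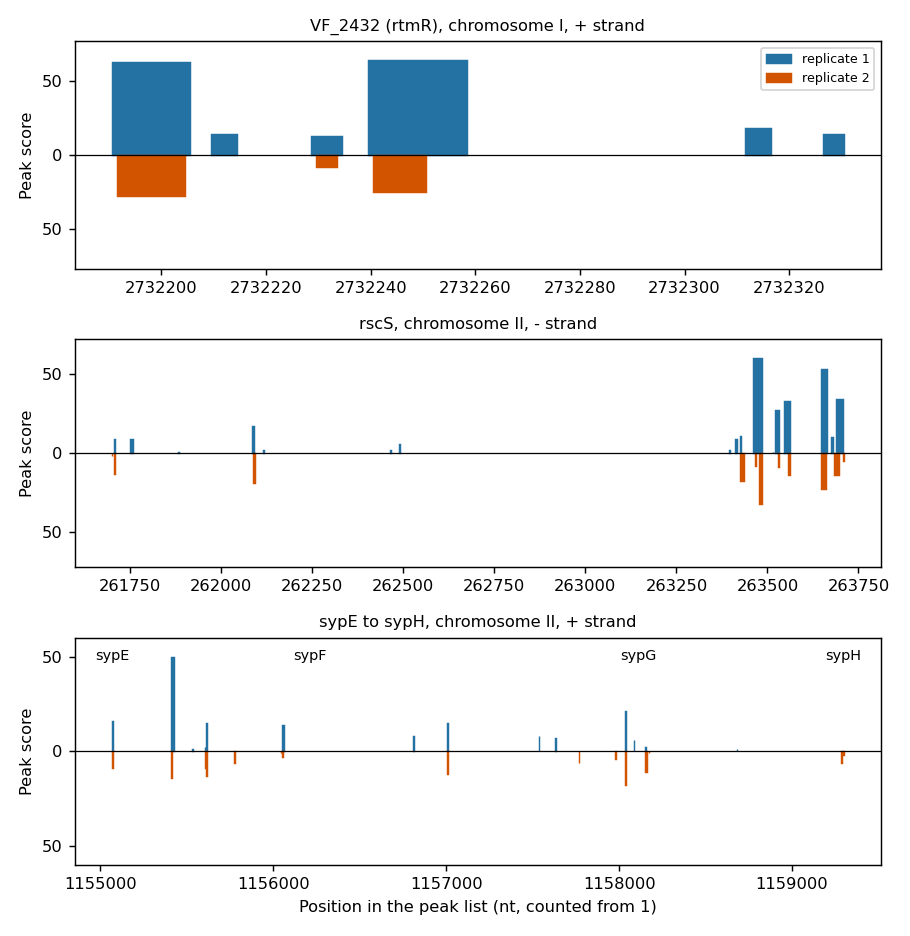
Peaks of replicate 1 (bars above the line) and replicate 2 (bars below the line) on VF_2432, rscS, and sypE to sypH. The x axis is the position in the peak list in nt, the bar width is the peak width, and the y axis is the authors' peak score, with the highest rscS peak of replicate 1 at 60.

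Of the remaining fixed lists, genes for cellulose synthesis had peaks in both replicates for 4 of 6 members (Fisher's exact adjusted p = 0.247). They were bcsA (VF_A0884), bcsB (VF_A0883), bcsZ (VF_A0882) and bcsG (VF_A0887). These peaks were weak in replicate 2, where the median score of all peaks was 10. There bcsA had 5 peaks, the highest scored 8, and bcsB and bcsZ had 1 peak each, scored 6. The only replicate 2 peak of bcsG covered 1 nt and scored 1. In the upper 50% of scores 0 of 6 cellulose genes had peaks in both replicates. With at least 2 peaks in each replicate 1 of 6 did. Light production and quorum sensing had peaks in both for 6 of 12 (Fisher's exact adjusted p = 0.564). In that list ainR (VF_1036), an autoinducer receptor, held 0.219% ± 0.042 of the score (SD, n = 2), luxS (VF_0545), an autoinducer synthase, held 0.0506% ± 0.010, and ainS (VF_1037) and luxO (VF_0937) held 0.0119% ± 0.00055 and 0.0108% ± 0.0017.

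The last comparison was between the replicates themselves. The same genes and positions recurred beyond chance. Of the genes of the reference table, 1968 had a peak in replicate 1, 1828 in replicate 2 and 1579 in both. Independent lists of these sizes would share 910, and 1579 is 1.74 times that. The expectation draws from all 3953 genes, whether or not their RNA was present, so the excess is no evidence of binding. By position, 4922 of 8899 peaks of replicate 1 (55.3%, exact 95% binomial interval 54.3% to 56.3%) overlapped a replicate 2 peak on the same strand by at least 1 nt, and 4986 of 7677 peaks of replicate 2 (64.9%, 63.9% to 66.0%) overlapped a replicate 1 peak. Random placement within the span of each gene's peaks gave 13.9% for replicate 1 and 16.1% for replicate 2, and circular shifts along the replicons gave 1.16% and 1.34% (one-sided permutation p = 0.001 for each, the smallest that 1000 draws can give).

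In 301 of 467 genes with at least 5 peaks in each replicate (64.5%), the highest peaks of both replicates overlapped. Keeping the highest replicate 1 peak and drawing a replicate 2 peak of the same gene at random, weighted by width, gave 25.1% (permutation p = 0.0001, the smallest that 10000 draws can give). Across 1587 genes with peaks in both, which are not independent replicates, summed scores correlated with a Spearman coefficient of 0.90 (95% bootstrap interval 0.888 to 0.913) and a Pearson coefficient of 0.88 on the log2 scale. The score shares of 77.3% of those genes lay within 2-fold of each other.

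**Figure D3:**
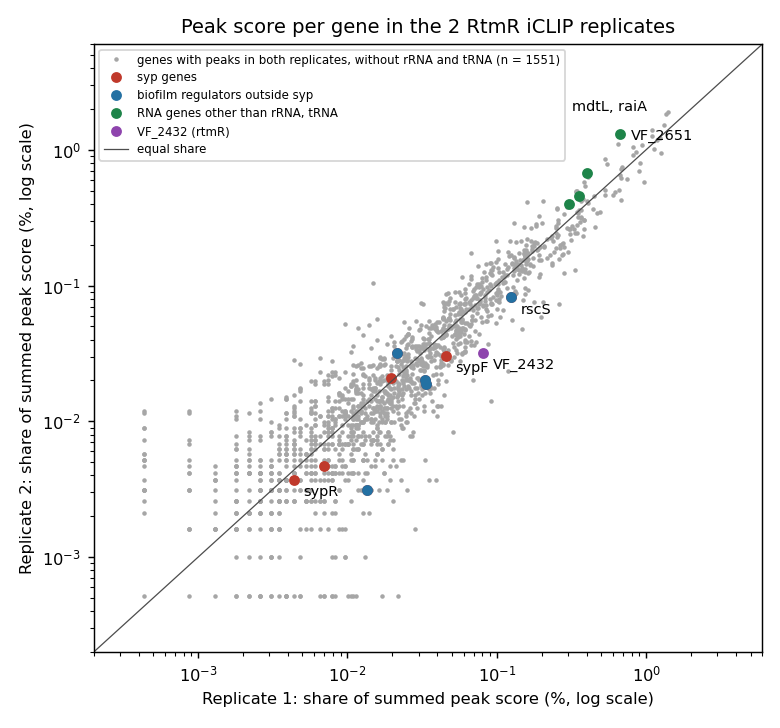
Share of summed peak score per gene in replicate 1 (x axis) and replicate 2 (y axis), both in percent on log scales, for 1551 genes with peaks in both replicates outside rRNA and tRNA genes. Coloured points are syp genes, other biofilm regulators, RNA genes and VF_2432, the line marks equal shares, and mdtL and raiA lie at the upper end in both replicates.

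Among the 200 genes of highest mean share, the log2 ratio of replicate 2 over replicate 1 had an SD of 0.50, and 94.5% of the genes lay within 2-fold. The genes furthest towards replicate 1 were cstA (VF_1147), a carbon starvation gene, at a log2 ratio of -1.83, ptsG (VF_1732), the glucose transporter of the phosphotransferase system, at -1.76, VF_A0363 at -1.45, ccoN (VF_1299), a cytochrome oxidase subunit, at -1.34, and sstT (VF_A0803) at -1.23. For cstA the summed score was 598 over 175 nt in replicate 1, 3.42 per nt, and 141 over 75 nt in replicate 2, 1.88 per nt. The genes furthest towards replicate 2 were the histidine degradation genes hutI (VF_A0453) at 1.38 and hutU (VF_A0451) at 1.36, VF_2577 at 1.15, VF_2593 at 1.10 and frdA (VF_2334) of fumarate reductase at 1.04. With 1 list on each side, these differences have no test.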

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

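No paired analysis was possible because there is 1 group. With 2 replicates, leaving one out gives no overlap or correlation, so those values have no such check. A lowest score of 5, the symbol and chromosome II backgrounds and the names of the peak lists were chosen after seeing the data. Not run were alternatives on gene windows, gene length, position in coding sequences and sequence, which need a genome of the lists' build. Read depth is unknown. The overlap stayed above all random placements under the score limits. It was 39.2% (replicate 1) and 45.4% (replicate 2) when 50% of each peak had to be shared, and 59.4% and 69.6% for midpoints within 10 nt, where random placement was not run. The Spearman coefficient was 0.84 in the top 10% of scores and 0.87 for highest peaks. Genes with peaks in both numbered 930 in the upper 50% and 315 in the top 10% of scores, which hold fewer peaks. Protein-coding genes held 97.0% of peaks in the upper 50% and 94.0% in the top 10% of scores, 93.3% of the summed score and 97.5% of covered nucleotides. RNA genes other than rRNA and tRNA held 0.424%, 1.74%, 2.23% and 0.383% by the same 4 measures, rRNA genes 0.168%, 0%, 0.121% and 0.207%, and tRNA genes 0.982%, 2.49% and 2.03% by the first 3. The cause was not tested. Of 17 lists, 11 passed the test, against 5 in the top 10% of scores. With genes that carry a peak in either replicate as background 3 passed (a test of whether peaks recur). With genes that have a symbol as background 7 of the 16 lists with members there passed. The flagellar list kept an odds ratio below 1 without passing in the top 10% of scores (0.54, fewer genes with peaks). The same held against genes with a peak in either replicate (0.64, fewer members). It also held with the names of the peak lists (0.51, which add genes with peaks). With those names the pilus list turned to 1.08. In the top 10% of scores, odds ratios above 1 turned to 0.95 for protein export, 0.9962 for RNA metabolism, 0.78 for biofilm regulators and 0.90 for cellulose, which was 0.25 in the upper 50%. With at least 2 peaks in each replicate cellulose was 0.71, light production and quorum sensing 0.96 and RNA metabolism 0.79. Against genes with a peak in either replicate RNA metabolism was 0.84 and the syp list turned to 1.23. Against genes with a symbol biofilm regulators were 0.74 (1 of only 2 members left), transporters 0.72 and RNA metabolism 0.89. Of these, only protein export and the pilus list had passed the test, and none passed after turning. Biofilm regulators passed with at least 2 peaks in each replicate (5.73). With 1 replicate left out, the odds ratio of the syp list ranged from 0.30 to 0.46, and the lower value, without replicate 2, passed, and that of light production and quorum sensing ranged from 0.96 to 1.53. For the replicate, class, replicon and 6 fixed list values, 71 of 110 alternative values held and 39 did not. For the added lists, highest peaks and named genes, 333 of 521 held and 188 did not. To hold meant the same direction and side of the threshold for tests, less than 1 replicate SD for shares, the bootstrap interval for correlations and a factor of 1.5 for counts. Shares with 1 replicate left out hold by construction, since 2 values lie within 1 SD of their mean. Where no cause is named above, it was not tested.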

Other observations

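The comparison of the chromosomes was chosen, and the runs below were listed, after the data had been seen. The predictions for the tests of gene symbols on the chromosomes, of neighbouring genes and of weak peaks were written before the results of those tests were seen. Genes with peaks in both replicates lay in runs of neighbours on 1 strand, 44 of which held at least 5 genes. The run with the most score, sdhC to sucD, held 8 genes of succinate dehydrogenase, 2-oxoglutarate dehydrogenase and succinyl-CoA synthetase and 3.66% ± 0.19 of the score outside rRNA and tRNA genes (SD, n = 2). The run bolA to nqrF, with the sodium-translocating NADH:quinone reductase, held 2.98% ± 0.37, the ribosomal run rpsQ to secY held 2.84% ± 0.10, and atpC to mnmG, with the ATP synthase genes, held 2.66% ± 0.13.

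The longest run, kpsF to VF_0201 on chromosome I, held 22 genes and 1.49% ± 0.053 of the score (SD, n = 2). Its named members include ddhA to ddhD and fnlA and fnlB, which carry names of sugar nucleotide synthesis for surface polysaccharides. A run of 10 genes from VF_0140 to VF_0149, with the sialic acid genes neuA, neuB, neuC and neuD, held 0.920% ± 0.14, and the run of cytochrome c maturation genes ccmI to ccmC held 0.708% ± 0.13. A run of 11 genes from mshI to mshA, named for the MSHA pilus, held 0.140% ± 0.016.

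Neighbouring genes carried peaks together in 873 pairs, against 670 on average and 742 at most in 10000 permutations of the genes within each replicon (permutation p = 0.0001, the smallest they can give). Chance placement of the genes is therefore argued against. Transcription of neighbours as 1 RNA of shared abundance is a candidate explanation that stays open, since no transcript map or input RNA was used here. No biological explanation was tested.

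Genes of chromosome II carried peaks in both replicates less often than those of chromosome I, 288 of 1151 (25.0%) against 1231 of 2541 (48.4%), an odds ratio of 0.36 (95% interval 0.304 to 0.414, Fisher's exact p = 2.353e-42 over genes). That p-value and interval also count neighbouring genes as independent. Fewer chromosome II genes have a symbol, 16.2% against 42.0%, so poorly characterised genes could account for the difference. Among genes with a symbol the odds ratio was 0.39 (0.283 to 0.538), which argues against that as the whole cause. Lower RNA abundance or shorter genes on chromosome II may still explain it and were not tested. No biological explanation was tested.

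Peaks found in 1 replicate only had a median score of 7 in replicate 1 and 6 in replicate 2, against 18 and 15 for shared peaks. The share of replicate 1 peaks overlapped by replicate 2 was 18.2% in the lowest 10% of scores and 98.7% in the top 10%, a difference of 80.4 percentage points. High peaks are wider, with a median width of 16 nt in the top 10% against 1 nt in the lowest 10%. Random placement within the span of each gene's peaks gave 6.55% in the lowest and 32.4% in the top 10%. The random value thus rose with the observed one, so width is not separated from score as a source of the rise. The predicted rise was found, and weak peaks near the limit of calling remain a candidate source of the peaks in 1 replicate only. Whether some weak peaks are specific to a replicate's culture stays open, and no biological explanation was tested.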
